A study of Mus musculus with 8 samples.

How the data were processed

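The study measured gene expression in mouse skin with Affymetrix Mouse Gene 1.0 arrays, in 4 wild-type and 4 Adam10 knockout samples. Per the labels, RNA was extracted on RNeasy columns and biotin-labelled cRNA was hybridised. The samples are described both as skin tissue and as primary skin cells, and the labels do not settle which applies. The titles mark the knockouts as cKO, a usual short form of conditional knockout, and carry a P with a number, 57 to 60 in wild type and 67, 68, 69 and 55 in knockouts 1 to 4. The labels do not say whether these are animals or days of age. The deposited values are 1 intensity per probe set and array, made by the authors with RMA (robust multi-array average) per the submitters' processing notes. RMA corrects background, makes the probe distributions of the arrays alike and summarises the probes of a probe set. Its version, settings and genome build are not given in the sources used here. RMA usually gives log2 values. These values ran from 0.817 to 11173 with array medians between 13.3 and 15.1, so they were read as linear intensities, and log2 of each value was taken with no pseudocount. No detection calls, probe-level values or scan dates were used, so background correction and scan batches were not tested.

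The table holds 35519 probe sets. The platform annotation gave exactly 1 gene symbol to 21780 of them, several to 1605 and none to 12134. Symbols were checked through Entrez identifiers against RefSeq genes of assembly GRCm38.p6, where 21689 of the 21780 matched and 0 symbols changed. Of 998 genes with more than 1 probe set the one with the highest mean over the 8 arrays was kept, which left 19935 genes, and no filter on dim genes was applied. The value of a gene is an average over probes along its transcript. Arrays give no depth, and the precision is limited by their number.

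Knockout was compared with wild type with limma 3.58.1 in R 4.3.3 (lmFit on genotype, then eBayes with default settings, two-sided), with Benjamini-Hochberg adjustment over all 19935 genes and a threshold of 0.05. Adjusted p-values in the text are from limma unless another test is named. Fold changes are knockout minus wild type on the log2 scale. The labels name 4 and 4 mouse tissue samples without saying that each came from a separate animal. The p-values therefore measure the spread between these samples. Adam10 was also tested with an exact two-sided permutation test over the 70 assignments of the arrays. The comparison, the 32 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined.

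The 32 lists hold 568 memberships, of which 523 were matched to a tested gene. The plan was to match by current or older symbol. An early run matched Pi3 to Serpina1c and Krtap16-1 to Krtap19-2, which are other genes, so older symbols were then accepted only where no other gene carries them and the letter root agrees. This change was made after an exploratory fit had been seen, and it left 0 matches by older symbol. Lists were tested with camera (limma) at a preset correlation of 0.01, adjusted over the 32 lists, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way. Sex-linked genes were kept outside this family as a check of the arrays. The genes named are Adam10, the 12 largest rises and 12 largest falls among genes that passed with no overlap between groups, and from each list up to 2 members that rose and 2 that fell, or the member with the smallest p where none passed. Predicted genes and olfactory or vomeronasal receptors were counted but not named. Where 5 or fewer members of a list passed in a direction, the rest are named too. These are Heyl, Jag2, Hbegf, Klk7, Dlx3, Dkk3, Krt17, Sox9, Fabp5, Far2, Mmp14, Ptch1 and Rnf43. They, with Skint2, Skint3 and Skint10 and the kinesins of the closing part, were chosen after their values were seen.

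The alternatives were quantile normalization, median centring, cyclic loess, 2 filters on dim genes, the mean of all probe sets of a gene, all probe sets with or without a name, a trended and robust prior, array weights, thresholds of 0.01 and 0.10, and leaving out each array in turn. After the data were seen, 4 more were added. They leave out wild-type arrays 3 and 4, add the mean of Eif2s3y, Kdm5d and Uty (genes of the Y chromosome) as a covariate, add the mean of the skeletal muscle list as a covariate, or take log2 of the value plus 16. The fit was tested on simulated data with 200 genes changed among 19935. It recovered 36% of changes of 0.5 on the log2 scale, 90% of changes of 1, 98% of changes of 2 and 98% of changes of 3, with 12 false calls among 173. A list shifted in the simulation was called, and 0 other lists were. The simulated genes varied independently, while in the real data the estimated correlation was 0.90 in the adipocyte list. The simulation therefore does not show how often camera at the preset correlation calls correlated lists wrongly.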

Results

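Expression was measured in 4 wild-type and 4 Adam10 knockout samples of mouse skin, 1 array per sample. Adam10 is a membrane protease that cleaves Notch receptors and other surface proteins, and the comparison asks which transcripts of the skin differ when it is lost. Array medians were 13.3 to 15.1 intensity units. Wild-type array 4 stood apart, with a mean correlation of 0.974 with the other wild-type arrays and a score of 61.18 on the first principal component (49.98% of the variance), against -24.91 to 17.52 on the other 7 arrays. Its muscle, fat and dermal markers were high. The skeletal muscle list lay at a median of 3.48 above the mean of all arrays on the log2 scale there, at 0.82 on wild-type array 3 and between -0.76 and -0.44 on the other 6. The sexes also differed in number. Eif2s3y, on the Y chromosome, lay near 2 on the log2 scale in 1 of 4 wild-type and 2 of 4 knockout arrays.

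Adam10 itself was lower in the knockout skin. Its mean log2 intensity was 7.28 ± 0.15 in wild type and 6.92 ± 0.12 in knockout (SD, n = 4), a difference of -0.36 with a standard error of 0.11, or 22.0% lower. All 4 knockout values lay below all 4 wild-type values, and the exact two-sided permutation p was 0.0286, the smallest that 70 assignments can give. The adjusted p over all genes was 0.064 in limma and missed the threshold. The titles call the knockouts cKO, usually short for conditional knockout, and neither the deleted exons nor the cells that lost them are stated, so how far this value measures the deletion is not known.

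Across 19935 genes, 1744 differed between the genotypes in limma, 1277 of them higher and 467 lower in the knockout. At least a 2-fold change was seen for 208 genes, 117 higher and 91 lower. The groups did not overlap for 3609 genes (18.1%), where chance gives 2.86%. The share of higher genes among those called was 73.2%. It was 63.0% after quantile normalization, 56.9% after cyclic loess and 89.6% after median centring, which moved the median of all genes to 0.10 on the log2 scale. The groups also differed in their spread of values. Log2 array medians were 3.73 to 3.82 in knockouts and 3.82 to 3.92 in wild type, and 75th percentiles 5.83 to 5.88 against 5.74 to 5.81. The median change was 0.11 for genes at or above the median level and 0.0027 for all genes. How far this sets the share of higher genes was not tested. Leaving out 1 array gave 992 genes without wild-type array 2, 750 without wild-type array 3, 911 without knockout array 1, 587 without knockout array 2 and 809 without knockout array 3. The count was 1914 without wild-type array 1, 1997 without wild-type array 4 and 1415 without knockout array 4. Without both wild-type arrays 3 and 4, 925 genes passed.

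The largest rises were in an epithelial cytokine, in keratins and envelope proteins of stressed epidermis and in a growth factor. Tslp, a cytokine made by keratinocytes that acts on dendritic and type 2 immune cells, rose from 1.60 ± 0.27 to 6.58 ± 0.56 (log2 intensity, SD, n = 4, adjusted p = 3.1e-05). Its wild-type values of 1.25 to 1.91 lay below the 25th percentile of their arrays (2.21 to 2.28), so the size of the rise is not settled. With those values set at that percentile the difference is 4.35. Rptn, an epidermal matrix protein of the cornified layer, rose by 4.88 on the log2 scale (SE 0.44, adjusted p = 0.00077). Krt16 rose by 3.66, Krt6b by 2.96 and Krt6a by 2.84, all keratins of wounded or hyperproliferating epidermis. The small proline-rich envelope precursors Sprr1a and Sprr1b rose by 3.47 and 2.59. Epgn, a ligand of the EGF receptor, rose 11.8-fold (log2 3.56, SE 0.21, adjusted p = 6.4e-05). The other large rises were Serpinb11 (2.41), Igfbp3 (2.36), Serpinb10 (2.20) and Pglyrp3 (2.16), a peptidoglycan recognition protein. Igfbp3 lost its call without knockout array 2 (adjusted p = 0.057) or knockout array 3.

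The largest falls included enzymes, myeloid genes and members of the Skint family, which are immunoglobulin-like proteins of keratinocytes. Aldh1a7, an aldehyde dehydrogenase, fell 7.51-fold (log2 -2.91, SE 0.21, adjusted p = 0.00041). Lyz2, the lysozyme of macrophages, was at 5.81 ± 0.81 in wild type and 3.39 ± 0.34 in knockout (adjusted p = 0.0042). Ano7 changed by -2.20, Serpinb3a by -2.06, Akr1d1 by -1.97, Abhd14b by -1.94 and Depp1 by -1.75. Ms4a4a and Ms4a6c, of a gene family active in myeloid cells, changed by -1.93 and -1.77. Gatm, an enzyme of creatine synthesis, changed by -1.92 and lost its call without wild-type array 3 or without knockout array 2, 3 or 4 (highest adjusted p = 0.083). Skint9 changed by -3.60 (SE 0.92, adjusted p = 0.040) and Skint4 by -2.05 (SE 0.56, adjusted p = 0.049). Both had a far lower value on knockout array 1 than on the other knockout arrays, 1.54 for Skint9 and 1.69 for Skint4. Skint9 lost its call without 5 of the 8 arrays in turn and Skint4 without 7, but without knockout array 1 both passed, at -2.42 (adjusted p = 0.0056) and -1.37 (adjusted p = 0.018).

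**Figure D1:**
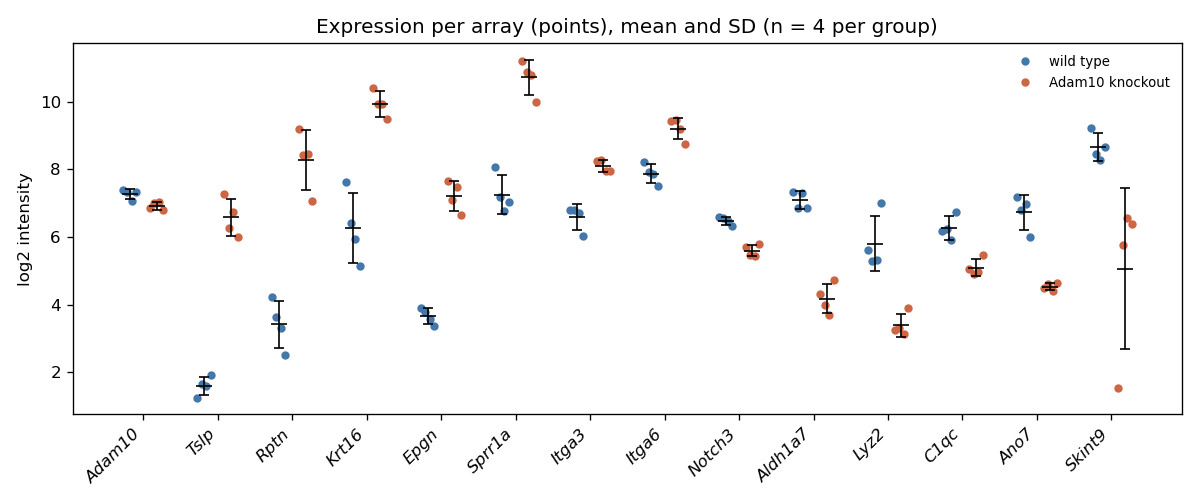
Log2 intensity (vertical axis) of 14 genes on each array, wild type in blue and Adam10 knockout in orange, with the mean and SD of each group (n = 4). Adam10 differed by -0.36, Tslp lay between 1.25 and 1.91 in wild type and between 6.01 and 7.28 in the knockouts, and Skint9 had 1 knockout value of 1.54 far below the others.

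Of the 32 gene lists, 12 passed in camera, 5 toward higher and 7 toward lower values in the knockout. With an estimated correlation between genes 0 of the 32 passed, and for each of the 12 that p is given beside it below. The Notch target list lost its call there with an estimated correlation of -0.072, below the preset 0.01. The loss of calls can therefore not be put down to correlation between genes alone, and what else contributed was not tested. By fry 8 passed (adjusted p 0.00043 to 0.021). They were the Notch target, basal keratinocyte, cell cycle, sebocyte, melanocyte, macrophage, Wnt and Hedgehog and immediate early lists. The muscle, adipocyte, dermal and endothelial lists passed in camera but not by fry (adjusted p 0.31 to 0.51). Without wild-type arrays 3 and 4, 11 lists passed in camera and 0 with an estimated correlation. They were not all the same lists. The muscle, dermal and endothelial lists no longer passed. The spinous (median -0.22, camera adjusted p = 0.018) and barrier lipid lists (median -0.24, camera adjusted p = 0.0013) passed toward lower values, which they had not with all arrays.

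Genes of basal keratinocytes, the cells that anchor the epidermis to its basement membrane, were higher in the knockout. Of 14 measured members 13 rose, 14 when adjusted over the list alone, with a median of 0.99 on the log2 scale (camera adjusted p = 2.2e-12). The adjusted p = 0.21 with an estimated correlation. The integrin chains Itga3 and Itga6 rose by 1.51 (SE 0.18) and 1.33 (SE 0.18). Without knockout array 2, 7 members passed. When wild-type arrays 3 and 4, which held more muscle or dermal signal, were left out, 10 members passed and the median was 0.84. Cell cycle genes rose alongside, 19 of 31 members over all genes and 25 adjusted over the list alone, with all 31 above 0 and a median of 0.52 (camera adjusted p = 3.9e-14, adjusted p = 0.18 with an estimated correlation). With that correlation and 1 array left out, the cell cycle list ran from 0.019 without knockout array 1, where it passed, to 0.33 without knockout array 4. Cenpe, a mitotic motor of the kinetochore, rose by 0.86 and Kif20a, a kinesin of cell division, by 0.77. Without knockout array 2, 10 cell cycle genes passed, and without wild-type arrays 3 and 4, 12 did.

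Differentiated keratinocyte genes gave calls in both directions. Of 12 spinous genes Sfn rose by 0.65 and Calml3 fell by 0.72, each passing over all genes, with 1 rise and 2 falls adjusted over the list alone (camera adjusted p = 0.11). The spinous list passed toward lower values without wild-type array 4 (median -0.22, camera adjusted p = 0.012, 0.57 with an estimated correlation) or knockout array 1, and reached 0.36 without wild-type array 1. Sfn lost its call without knockout array 1 or 3 and Calml3 without 5 of the arrays in turn. Of 24 granular and cornified envelope genes Rptn, Lce3c (1.49) and Klk7 (0.48) rose and Casp14, the protease that processes filaggrin, fell by 0.75, with 4 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.16). The granular list passed toward higher values without wild-type array 1 (median 0.15, camera adjusted p = 0.023, 0.68 with an estimated correlation) or 3, and reached 0.95 without wild-type array 4, where 3 members rose and 3 fell. Lce3c lost its call without knockout array 2, Klk7 without 5 of the arrays in turn and Casp14 without 4. Among 16 barrier lipid genes Alox12e, an epidermal lipoxygenase, fell by 1.03 and was the 1 member that passed both ways of adjusting (camera adjusted p = 0.16). With wild-type array 4 left out, 3 of them fell and the list passed toward lower values (median -0.25, camera adjusted p = 0.0023, 0.59 with an estimated correlation), while it reached 0.58 without wild-type array 1. Of 25 keratinocyte stress genes and alarmins 7 rose and Serpinb3a fell, with 8 rises and 1 fall adjusted over the list alone. That list's mean of 0.59 and median of -0.09 differ in sign, and it did not pass (camera adjusted p = 0.25).

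Among 11 Notch target genes 3 fell and 0 rose, with the same counts adjusted over the list alone. Notch3 changed by -0.89 (SE 0.11, adjusted p = 0.0025), Nrarp by -0.62 (SE 0.14) and Heyl by -0.57 (SE 0.14). The list median was -0.19 (camera adjusted p = 0.0047, adjusted p = 0.18 with an estimated correlation). The correlation estimated for this list was -0.072, below the preset 0.01, so higher correlation among its own genes did not raise that p. Nrarp lost its call without 5 of the arrays in turn and Heyl without 6, while 1 member passed without wild-type array 2. Of 21 Notch receptors, ligands and modulators 3 rose, 5 adjusted over the list alone. Lfng, a glycosyltransferase that modifies Notch, rose by 0.99, and the ligands Dll1 and Jag2 rose by 0.95 and 0.91. The list did not pass (camera adjusted p = 0.21). Of 13 EGF receptor family genes and ligands Epgn, Ereg (2.10) and Hbegf (0.93) rose and the ligands Btc (-0.996) and Nrg4 (-0.76) fell, with 4 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.26). Among 18 other ADAM proteases and partners Adam8 rose by 1.82 (SE 0.16) and Adam19 changed by -0.52, with 2 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.55). Adam19 lost its call without 7 of the arrays in turn.

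Macrophage and monocyte genes were lower in the knockout. Of 18 members 9 fell and 0 rose, 12 falls adjusted over the list alone, with a median of -0.85 (camera adjusted p = 2.5e-10). The adjusted p = 0.29 with an estimated correlation. C1qc, a complement chain made by macrophages, changed by -1.17 (SE 0.18). Wild-type array 4 was highest, at 0.90 above the mean of all arrays, and wild-type arrays 1 to 3 lay at 0.21 to 0.25 against -0.55 to -0.17 in the knockouts. With wild-type arrays 3 and 4 left out, 9 members fell and the median was -0.70. Of 12 Langerhans and dendritic cell genes the class II gene H2-Ab1 rose by 1.38 and the adhesion molecule Epcam by 0.57, with 5 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.28). Epcam lost its call without 6 of the arrays in turn. Kit, a receptor of mast cells and melanocytes, rose by 1.09 and was the 1 member of 11 mast cell genes that passed either way of adjusting. The mast cell list had a median of -1.24 and missed the threshold (camera adjusted p = 0.073). It passed without wild-type array 1, 2 or 4, lowest without array 2 (camera adjusted p = 0.010, 0.61 with an estimated correlation) and highest without knockout array 3 (0.12), and its median was -0.64 without wild-type array 4, where 3 members fell and 1 rose. With wild-type arrays 3 and 4 left out, 2 fell and 1 rose, the median was -0.17 and the list did not pass (camera adjusted p = 0.11). Relative to the mean of all arrays the list lay at 2.42 on wild-type array 4 and 0.25 on wild-type array 3. It lay at -0.30 and -0.29 on wild-type arrays 1 and 2 and between -0.70 and -0.54 in the knockouts. In the neutrophil (13 measured), T and NK cell (18) and B and plasma cell (9) lists 0 members passed over all genes and 0 adjusted over the list alone, with camera adjusted p = 0.20, 0.52 and 0.60. The members with the smallest p there were Camp (-0.45), Cd5 (0.26) and Cd79b (-0.20).

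Among 18 type 2 and epithelial cytokine genes Tslp and Il33 (1.15), an alarmin cytokine, rose, with 2 rises adjusted over the list alone (camera adjusted p = 0.81). Of 24 inflammatory cytokines and chemokines the chemokine Cxcl14 rose by 0.79 (1 rise adjusted over the list alone, camera adjusted p = 0.76), and it lost its call without knockout array 2 or 3. Of 21 interferon-stimulated genes the transcription factor Irf7 rose by 1.43 (1 rise adjusted over the list alone, camera adjusted p = 0.36), and it lost its call without 5 of the arrays in turn and without both wild-type arrays 3 and 4. Of 15 wound and matrix genes Tnc (1.97), Cd44 (0.91) and Mmp14 (0.64) rose and Vegfa (-0.70) fell, with 5 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.40). Mmp14 lost its call without knockout array 2 and Vegfa without 5 of the arrays in turn.

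Immediate early and heat shock genes, which also respond to handling of tissue, were higher in the knockout. Of 15 members 8 rose and Hsph1 fell (-0.46), the same counts adjusted over the list alone, with a median of 0.50 (camera adjusted p = 2.7e-05, adjusted p = 0.20 with an estimated correlation). The transcription factors Atf3 and Jun rose by 1.34 and 1.03. Hsph1, a heat shock protein, lost its call without 7 of the arrays in turn. Of 10 melanocyte genes 6 rose, 7 adjusted over the list alone, with a median of 0.64 (camera adjusted p = 2.7e-05). The adjusted p = 0.40 with an estimated correlation. Gpnmb and Mlana, proteins of melanosomes, rose by 1.15 and 1.01.

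Hair follicle and gland genes gave calls in both directions. Of 17 Wnt and Hedgehog response genes 5 rose, 11 rises and 1 fall adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.0012, adjusted p = 0.44 with an estimated correlation). They were Znrf3 (0.78), Smo (0.70), Ptch1 (0.68), Rnf43 (0.62) and Lef1 (0.61), and 1 of the list passed without knockout array 2. Of 16 hair follicle stem cell and outer root sheath genes Lgr6 (0.81), Lhx2 (0.65), Sox9 (0.65), Krt17 (0.63) and Dkk3 (0.62) rose, 10 rises and 3 falls adjusted over the list alone (camera adjusted p = 0.11). Of the 8 fits with 1 array left out, Lef1 and Sox9 lost their calls in 5, Lhx2 in 4, Lgr6 and Znrf3 in 2, Rnf43 in 3 and Ptch1 in 6. With wild-type arrays 3 and 4 left out, 1 Wnt and Hedgehog gene rose, and 2 hair follicle stem cell genes rose and 1 fell. Of 31 hair shaft and inner root sheath genes Lef1, Krt32 (0.60) and Dlx3 (0.45) rose and Krt73 (-1.08) and Tchh (-0.78) fell, with 5 rises and 3 falls adjusted over the list alone (camera adjusted p = 0.52). Dlx3 lost its call in 7 of those fits, and Krt73 and Tchh in 1, without knockout array 2. Of 17 sebocyte genes 4 fell, 5 adjusted over the list alone, with a median of -0.39 (camera adjusted p = 6.1e-05, adjusted p = 0.18 with an estimated correlation). They were Mgst1 (-1.69), Elovl3 (-1.02), Fabp5 (-0.60) and Far2 (-0.59), and 0 passed without knockout array 2. Mgst1, Fabp5 and Far2 lost their calls in 6 of the 8 fits and Elovl3 in 1. Mgst1 was at 7.54 on wild-type array 4, against 5.33 to 5.41 on the other wild-type arrays.

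The lists of tissues below the epidermis were lower in the knockout by camera but did not pass by fry (adjusted p 0.31 to 0.51). They held 0 called members, both over all genes and adjusted over the list alone. Skeletal muscle had a median of -1.41 (18 genes, camera adjusted p = 9.4e-05, adjusted p = 0.64 with an estimated correlation). Adipocyte genes had -0.99 (12 genes, camera adjusted p = 0.0027, adjusted p = 0.64 with an estimated correlation). Dermal fibroblast genes had -0.93 (18 genes, camera adjusted p = 0.0074, adjusted p = 0.64 with an estimated correlation) and endothelial genes -0.67 (14 genes, camera adjusted p = 0.0039, adjusted p = 0.64 with an estimated correlation). Without wild-type arrays 3 and 4 these medians were -0.14, -0.20, -0.03 and -0.08, where the adipocyte list still passed (camera adjusted p = 0.0065, 0.31 with an estimated correlation) and the muscle (0.086), dermal (0.70) and endothelial (0.34) lists lost their calls. The dermal list also lost its call without wild-type array 4 alone (adjusted p = 0.26), where the other medians were -0.56 for muscle, -0.18 for adipocyte and -0.22 for endothelial genes. With array 4 left out 2 dermal genes rose, 2 adipocyte genes fell and 1 endothelial gene fell, and with arrays 3 and 4 left out 3 dermal genes rose and 1 adipocyte gene fell. The members with the smallest p in all 8 arrays were Acta1 (-2.40), Lipe (-0.52), Fn1 (0.41) and Lyve1 (-1.12). The Schwann cell list (7 genes, Sox10 0.42) and the erythroid list (4 genes, Slc4a1 -0.32) held 0 called members either way, with camera adjusted p = 0.73 and 0.21. The erythroid list passed without wild-type array 3 (median -0.45, camera adjusted p = 0.040, 0.27 with an estimated correlation) and reached 0.39 without wild-type array 1, and 1 member fell without wild-type arrays 3 and 4.

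**Figure D2:**
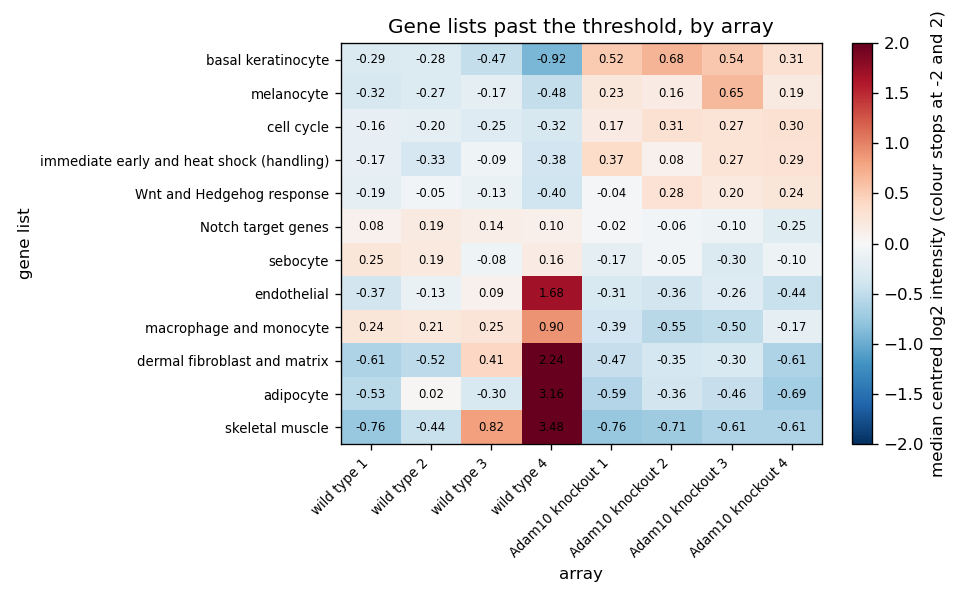
Median centred log2 intensity of the members of each list that passed in camera (rows) on each array (columns), where 0 is the mean of the 8 arrays and colour stops at -2 and 2. Basal keratinocyte genes lie between 0.31 and 0.68 in the knockouts and between -0.92 and -0.28 in wild type, while skeletal muscle reaches 3.48 on wild-type array 4.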

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

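The tests of tissue makeup, of macrophages and of the Skint genes below were chosen after the results were seen. Those of the splits and of sex were chosen before their own results, the one of sex after the data had been seen. The number of genes called exceeded what regrouping gives. The real split of the 8 arrays gave 1744 genes in limma, and of the 35 splits 1 gave as many, the real one. That met the bound set against chance, but 1 of 35 is the smallest share possible, so chance is not excluded. Every other split mixes the genotypes, so a difference between them of any cause widens the spread within its groups. The highest of the other 34 gave 0 genes, with at most 2395 at an unadjusted p under 0.05 against 5008 in the real split.

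Basal keratinocyte genes were higher in the knockout, and less muscle, fat and dermis in those samples could raise every epidermal class. That explanation needs basal and differentiated genes to rise alike. The basal median minus the spinous and granular median was 0.96 higher in the knockout, and the basal median stayed at 0.84 without wild-type arrays 3 and 4. The exact two-sided permutation p of that difference was 0.0286, the smallest possible. The basal list was taken up because it differed on these same arrays, so that p adds little support of its own. With the Y-linked level as a covariate the basal median was 1.00, which argues against unequal sexes. A change in the epidermis of the knockout stays open as a hypothesis. Sampling site, age and hair cycle also stay open, for the other results above too, and were not tested. If the P numbers of the titles are days, age would differ between the groups. They are 57 to 60 in wild type and 67, 68, 69 and 55 in the knockouts. Knockout array 4, number 55, had the lowest knockout values of Tslp (6.01), Rptn (7.07) and Krt16 (9.49), all above every wild-type value. Its basal (0.31) and macrophage (-0.17) medians were also the nearest to wild type among the knockouts. For Pglyrp3 and the cell cycle list another knockout array was lowest, and 1 array cannot tell age from other differences.

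Macrophage genes were lower in the knockout, and more dermis in the wild-type samples could carry more dermal macrophages. On wild-type arrays 1 and 2, where the muscle medians of -0.76 and -0.44 lay near the knockouts' -0.76 to -0.61 and the dermal medians of -0.61 and -0.52 at or near their -0.61 to -0.30, the list still differed, with knockouts at -0.70 relative to those arrays. Fat stays open, since wild-type array 1 had an adipocyte median of -0.53, inside the knockouts' -0.69 to -0.36, with a macrophage median of 0.24 against their -0.55 to -0.17, but it is 1 array, and wild-type array 2 lay at 0.02 for fat and 0.21 for macrophages. For a loss of immune cells of every kind, the lowest median of the 5 other immune lists without wild-type arrays 3 and 4 was -0.17, above the bound of -0.3 set against it, but by a condition added after that value was seen it stays open, since 5 of their 63 members lay at or above the median gene (4.45) on wild-type arrays 1 and 2. Fewer macrophages, or lower expression in them, may explain the pattern, and the data do not separate these.

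Of 7 Skint genes measured 4 fell in the knockout, and a sequence variant or cross-hybridisation in their cluster may contribute. Skint9 was at 1.54 and Skint4 at 1.69 on knockout array 1, where the other knockouts lay at 5.77 to 6.56 and 4.28 to 4.70, and the largest range within a group was 5.02. For Skint2 and Skint10, which changed by -1.29 and -1.32, the ranges within the knockouts were 1.04 and 1.25, between the bounds set for the test, while 35 other spinous and granular genes had a median of 0.016. Skint3, which lies between Skint4 and Skint9 by gene order, was at 1.30 on knockout array 1 and missed the threshold (adjusted p = 0.060). Without knockout array 1 Skint9 (-2.42), Skint4 (-1.37), Skint2 (-1.34), Skint10 (-1.06) and Skint3 (-1.63) passed (adjusted p = 0.0056 to 0.030), so that array alone does not make the difference, but a variant and an effect of genotype cannot be told apart with no genotypes of this segment.

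Of 252 groups of 4 arrays tested, 21 had a value far from the others, where chance gives about 13. On wild-type array 4, Itga3 was at 6.04, Sfn at 9.72, Alox12e at 6.69, Mgst1 at 7.54, Lyve1 at 6.05 and Gpnmb at 4.69, and the list medians of stress genes, adipocyte and macrophage genes were -0.34, 3.16 and 0.90 relative to the mean of all arrays. Wild-type array 1 had Tnc at 6.41 and Eif2s3y at 2.38, and wild-type array 3 had Adam10 at 7.06. Knockout array 4 had Serpinb3a at 6.24, Adam19 at 3.79 and Gpnmb at 5.63. Knockout array 3 had Btc at 5.88 and list medians of -0.0010 for ADAM proteases, -0.23 for barrier lipids and 0.65 for melanocytes. Among 13739 probe sets with no single gene symbol, which the comparison by gene left out, 195 (1.42%) passed when all probe sets were tested together, 116 higher and 79 lower. The share among named probe sets in that fit was 4.15%.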

How the results depend on the processing

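No paired analysis was possible because the replicate numbers follow the order of the samples and pair nothing. Leaving out wild-type arrays 3 and 4, the 2 covariates and log2 of the value plus 16 were chosen after the data were seen. Up to 20 alternatives were run per gene. Of the 24 genes with the largest changes 20 kept direction and threshold under every alternative in which they were tested. Of 67 named by the rule that passed 44 did. A gene that a dim filter removed was not tested under that filter and was counted by its other alternatives. Counts of genes changed, higher, lower and at least 2-fold were 1744, 1277, 467 and 208. Where they moved by over 1.5 times, median centring gave 2739 changed, 2453 higher and 286 lower, array weights 3621, 2405 and 1216, all probe sets 1099, 792 and 307, a threshold of 0.01 gave 478, 350 and 128 and one of 0.10 gave 2958, 2060 and 898. Higher genes numbered 847 after quantile normalization and 769 after cyclic loess. Without wild-type arrays 3 and 4, 925 changed and 591 were higher, and log2 of the value plus 16 gave 91 genes of at least 2-fold. Leaving out 1 array gave 587 to 1997 changed, 426 to 1417 higher, 161 to 647 lower and 157 to 244 of at least 2-fold. Other thresholds and the added constant act by construction. Leaving out 1 array moved the counts both ways, and the cause of that and of the other shifts was not tested. Adam10 stayed between -0.43 and -0.32 when 1 array was left out, with no adjusted p past the threshold. It passed at -0.46 after quantile normalization (0.033), at -0.49 after cyclic loess (0.027) and at -0.32 with the added constant (0.037). The cause of those shifts was not tested. Adam10 also passed at an unchanged -0.36 with either dim filter (0.031 and 0.046) or the trended and robust prior (0.049). The filters and the prior change the genes fitted and adjusted over or the variance estimate, and leave the values of Adam10 as they are. Lists past the threshold numbered 12 to 14 when 1 array was left out and 0 with an estimated correlation, or 1 where knockout array 1 was also left out.

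Some lists changed direction in the list test, and their medians were these. Of the lists that had passed, dermal fibroblast genes had -0.035 without wild-type arrays 3 and 4 and 0.020 with the muscle covariate, where endothelial genes had 0.062. The others had not passed and did not pass there. With the muscle covariate ADAM proteases had -0.013, granular genes -0.12, Schwann cell genes 0.10 and type 2 cytokines 0.045. By fry ADAM proteases had -0.11 and type 2 cytokines -0.085. With array weights hair shaft genes had 0.054, Schwann cell genes 0.0093, B cell genes 0.071 and type 2 cytokines -0.074. After quantile normalization T cell genes had 0.038, B cell genes 0.030 and type 2 cytokines -0.025, and after cyclic loess 0.013, 0.035 and -0.027. Without wild-type arrays 3 and 4 Schwann cell genes had 0.092 and type 2 cytokines 0.021. With the percentile filter inflammatory cytokines had -0.033. Leaving out 1 array also turned some, with medians from -0.075 to 0.15 for granular genes, -0.16 to 0.19 for Schwann cell genes, -0.10 to 0.029 for T cell genes, -0.058 to 0.053 for B cell genes, -0.11 to -0.013 for type 2 cytokines and -0.046 to 0.055 for inflammatory cytokines. The cause was not tested. With no detection calls, signal over background could not be set for dim genes.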

Other observations

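The symbol-family test and the windows of neighbouring genes were not among the planned comparisons, and the family test was chosen after the data were seen, the window test before its result. Kinesins, motor proteins of which many move chromosomes in mitosis, held a larger share of rises than the other genes tested. Families were defined by the root of the gene symbol, and 345 families of at least 8 genes were tested for excess rises and excess falls with a one-sided Fisher's exact test, adjusted over 690 tests. Only the kinesins passed, with 14 of 38 genes rising, 0 falling and a family median of 0.14 on the log2 scale (adjusted p = 2.8e-05). The test treats genes as independent draws, which genes acting together in mitosis need not be. Its p therefore does not measure the spread between samples. Kif13a rose by 0.89, Kif23 by 0.86, Kif20b by 0.86 and Kif2c by 0.82 on the log2 scale. Kif11 and Kif20a are also members of the cell cycle list, whose camera adjusted p was 3.9e-14, and 0.18 with an estimated correlation. Without wild-type arrays 3 and 4, 8 kinesins rose.

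A strain segment that travels with the targeted locus would crowd the changed genes around Adam10. By gene order in GRCm38.p6, 13 of the 100 tested genes nearest to Adam10 changed. The 95th percentile of 365 windows of 100 neighbouring tested genes was 14, and the windows' median was 9. The share near Adam10 was thus not above that bound, and a smaller segment was not tested.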
